A study of Homo sapiens with 2 samples.

How the data were processed

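Total RNA of cells differentiated from the H1 embryonic stem cell line was sequenced in 2 libraries of 1 group, harvested at day 16. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols, which do not say whether strand was kept. They also do not say whether the 2 replicates were separate differentiations, so the spread between them may be technical. The authors deposited FPKM (fragments scaled to transcript length and to the number of mapped fragments) for each library in a single table. Reads were aligned with HISAT2 to GRCh38, per the submitters' processing notes, and the aligner's version, the quantifier, the annotation and any filter are not given in the sources used here. How reads shared between overlapping genes or near-identical copies were divided is therefore unknown, and levels of such genes are uncertain, whether or not this is repeated beside the value. Of the genes named in the text, ETV4, SOX10, PAX9, KRT8, KRT18, SCNN1A, TAGLN, ACTA2, KRT10, POU5F1, TUBB3, PAX6, ERBB3, TNNT2, TGM2, STRA6, CCND1, AXIN2, ERBB2, FGFR1, HOXB3, HOXB4, HOXB6, HOXC6, TYMS, ALDOA, CA9, TFPI2, HLA-C, MEST, PEG10, STAR, CYP17A1, F11R, TNC, FTH1, INO80B-WBP1, AL162417.1, AL355312.5, BIVM-ERCC5, RPL36A-HNRNPH2, AC023055.1 and AC131160.1 overlap an exon of another gene on either strand. HLA-C, HLA-G, AMY1A, AMY1B, the CGB genes and the retroviral envelope genes were taken to have near-identical copies, without a comparison of sequences. FTH1, FTL, EEF1A1, ACTB, GAPDH and ribosomal protein genes have processed copies.

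The table holds 22811 features: 19974 with Ensembl identifiers, all of which matched GENCODE release 29 (19922 protein coding), and 2837 unnamed features that the authors call new genes. In 15 rows the symbol repeats an earlier row, and the first listed was used. Coordinates are GRCh38 from GENCODE 29, counted from 1. The deposited FPKM summed to 359845 and 356688, with 4229 and 4199 features at 0. For genes with 1 annotated transcript, FPKM times length gathered at whole multiples of 0.0598 and 0.0535, which gives the depth estimates of about 16700000 and 18700000 fragments. Within 0.02 of a fragment of a whole number from 1 to 5 lay 22.0% and 21.6% of low values, against 3.15% and 2.64% on a grid shifted between whole numbers, so reads were not recovered and no statement rests on a test of counts. A chi-square of estimated fragments, made to ask whether both columns held the same library, gave 5682 on 661 degrees of freedom over 662 genes, but it rests on these rounded estimates and was not used. Of 19633 features above 0 in either library, 0 held exactly equal values in both, and the libraries were kept as separate samples. Floors cover counting error only. All 77 ribosomal protein genes were above 0, and 3 of 120 genes of essential families were listed at 0 (PSMB9, PSMA8 and PSMB11, subunits of specialised proteasomes).

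Levels were analysed as log2(FPKM + 0.1), which understates differences of low genes. Detection meant FPKM of at least 1 in both libraries. With 1 group and no control sample among those analysed, no p-value was computed. The 34 gene lists of the report (17 of them lineages), its comparisons, the rule for named genes and the alternatives other than annotated genes alone were fixed before the data were examined. Further gene groups and some tests of explanations, named where they are given, were chosen later. Each list's median was placed among 10000 random lists of equal size from all features. Its difference between libraries, over members with mean FPKM of at least 1, was placed among 10000 lists matched on level in 10 bins, where at least 3 members passed. Named genes were up to 4 highest members of each list and up to 3 low ones, the 20 most abundant genes, the 10 largest differences each way, the 15 highest of transcription factor families taken by the start of the symbol, the 10 highest keratins and HOX genes of at least 1 FPKM. The symbol rule also took ENO1, ENC1, IDH1 and IDH2, which are not such factors. Some further list members were named after their values were seen, and some genes that the rule takes are not reported here.

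Alternatives were pseudocounts of 0.01 and 1, other limits on low values, centring, rescaling to equal sums (as in TPM) with limits kept, another background, unshared list genes, means for medians and leaving out each library. Annotated genes alone were added after seeing the data. On data simulated from the mean levels with counting error only, 100 of 100 genes changed 4-fold and 100 of 100 changed 8-fold were recovered. In that simulation 13 of 12448 unchanged genes were called more than 2-fold apart. Differences of preparation or of read assignment were not simulated, so this gives no error rate for the 185 genes called in the real libraries. Of 100 random lists 3 reached the 95th percentile, and of 100 lists raised by 5 on the log2 scale 96 did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.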

Results

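RNA from cells differentiated from H1, a human embryonic stem cell line, was sequenced at day 16 in 2 libraries of a single group labelled salivary gland epithelial progenitors. Aggregates were moved to adherent plates at day 3. BMP4 at 10 pM was given from day 5 to day 10, retinoic acid at 1 µM for 2 days from day 10, and CHIR99021, a GSK3 inhibitor that activates WNT signalling, at 6 µM for 4 days. The controls of the design are published datasets, which were not analysed here, so levels are described within the 2 libraries and no change from the starting cells can be given. Values are deposited FPKM, written as mean ± SD over the 2 libraries (n = 2). Depth was estimated from the spacing of low values at about 16700000 fragments in library 1 and 18700000 in library 2, where 3 fragments of a 2 kb transcript correspond to 0.0896 and 0.0802 FPKM.

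The first question was which genes these cells transcribed. Among the most abundant transcripts outside the mitochondrial genome, EEF1A1, a translation elongation factor, reached 3238 and 4903 FPKM in libraries 1 and 2, FN1 (fibronectin) 3175 ± 143, ACTB 3120 ± 38.3, FTH1 (ferritin heavy chain) 2673 ± 253 and TPM1 (tropomyosin) 1584 ± 5.23. FTL (ferritin light chain) stood at 1746 ± 34.3 and GAPDH, a glycolytic enzyme, at 1494 ± 129. MDK, a heparin-binding growth factor, stood at 979 ± 70.7 and ANXA2 at 975 ± 58. In all, 12306 of 22811 features (53.9%) had FPKM of at least 1 in both libraries, of which 11725 carried Ensembl identifiers and 581 were unnamed features that the file calls new genes. No test was made, since the series holds 1 group.

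The next question was how far the cells transcribed the genes of a salivary epithelial progenitor. On the list for that state, 8 of 14 genes had FPKM of at least 1 in both libraries. FGFR2, the receptor through which FGF10 drives gland budding (ENSG00000066468, chromosome 10, 121478334 to 121598458, GRCh38), was highest at 39.4 ± 6.83 FPKM, followed by SOX9 at 15.5 ± 1.15, ETV4 at 10.6 ± 1.13 and EYA1 at 8.74 ± 0.524. TP63, a basal epithelial factor, stood at 5.42 ± 0.811, KIT at 2.48 ± 0.201 and the basal keratin KRT14 at 1.37 ± 0.467. SOX10 was listed at 0 and 0.0186 in the 2 libraries, KRT5, the usual partner of KRT14, at 0.0893 and 0.0216, and KRT15 at 0.297 and 0.223. The list's median of log2(FPKM + 0.1) was 0.94 ± 0.29, at percentile 51 of 10000 random lists of equal size. That percentile was 11 against genes with mean FPKM of at least 0.1 and 36.1 against annotated genes, a background chosen after seeing the data.

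Genes of the oral ectoderm, the tissue from which gland epithelium buds, were detected for 9 of 14 members. TFAP2A was at 52.6 ± 12.1 FPKM, ISL1 at 14.7 ± 0.659, DLX3 at 11.8 ± 2.15 and the oral and pituitary factor PITX1 at 11.5 ± 0.802. SHH (0.127 and 0.0352), PAX9 (0.0146 and 0.110) and FOXE1 (listed at 0 in both) were at or near the floor. The list's median was 2.71 ± 0.14, at percentile 90.5, or 67.4 against genes with mean FPKM of at least 0.1. Of the 14 members, 5 also stand on another lineage list, among them ISL1 on the amnion list, so these levels do not single out oral ectoderm.

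Genes of differentiated gland cells were mostly low. Of the acinar and secretory list, 1 of 21 members was detected (the chloride cotransporter SLC12A2, 9.11 ± 0.578 FPKM), while AQP5, the water channel of acinar cells, and the amylase genes AMY1A and AMY1B were listed at 0 in both libraries. BHLHA15 passed 1 FPKM in library 2 alone (0.799 and 1.76). Duct genes were detected for 7 of 16 members, led by KRT7 (663 ± 10.1), KRT19 (532 ± 10.2), WFDC2 (15.9 ± 0.632) and SCNN1A (9.30 ± 1.54), with KLK1, ASCL3 and FOXI1 at 0. Myoepithelial genes were detected for 9 of 10, led by TAGLN (1046 ± 170), ACTA2 (162 ± 19.7), CNN1 (126 ± 5.85) and the keratin KRT17 (57.1 ± 4.22); TAGLN, ACTA2 and CNN1 are contractile genes that smooth muscle also uses. The medians lay at percentiles 0, 11.6 and 99.7. The duct percentile was 5.37 without replicate 2 and 0.050 against genes with mean FPKM of at least 0.1.

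Pan-epithelial genes were detected for 15 of 15 members, with a median of 7.01 ± 0.06 at percentile 100. The simple epithelial keratins led: KRT8 at 2044 ± 92.3 FPKM, KRT18 at 1432 ± 279, KRT7 and KRT19 as above. KRT8 and KRT18 overlap in the annotation, so their reads are uncertain between them. Among 10 keratins with mean FPKM of at least 1, KRT23 (28.6 ± 2.44), KRT80 (9.32 ± 0.278), KRT10 (7.86 ± 1.45) and KRT16 (1.32 ± 0.236) completed the set. Epidermal genes were detected for 2 of 13 members (KRT10 and TGM1, the latter at 5.25 ± 0.830), with KRT1, LOR and SPRR1A at 0 and the median at percentile 1.00, or 2.07 without replicate 2, 2.00 against annotated genes and 0 against genes with mean FPKM of at least 0.1.

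**Figure D1:**
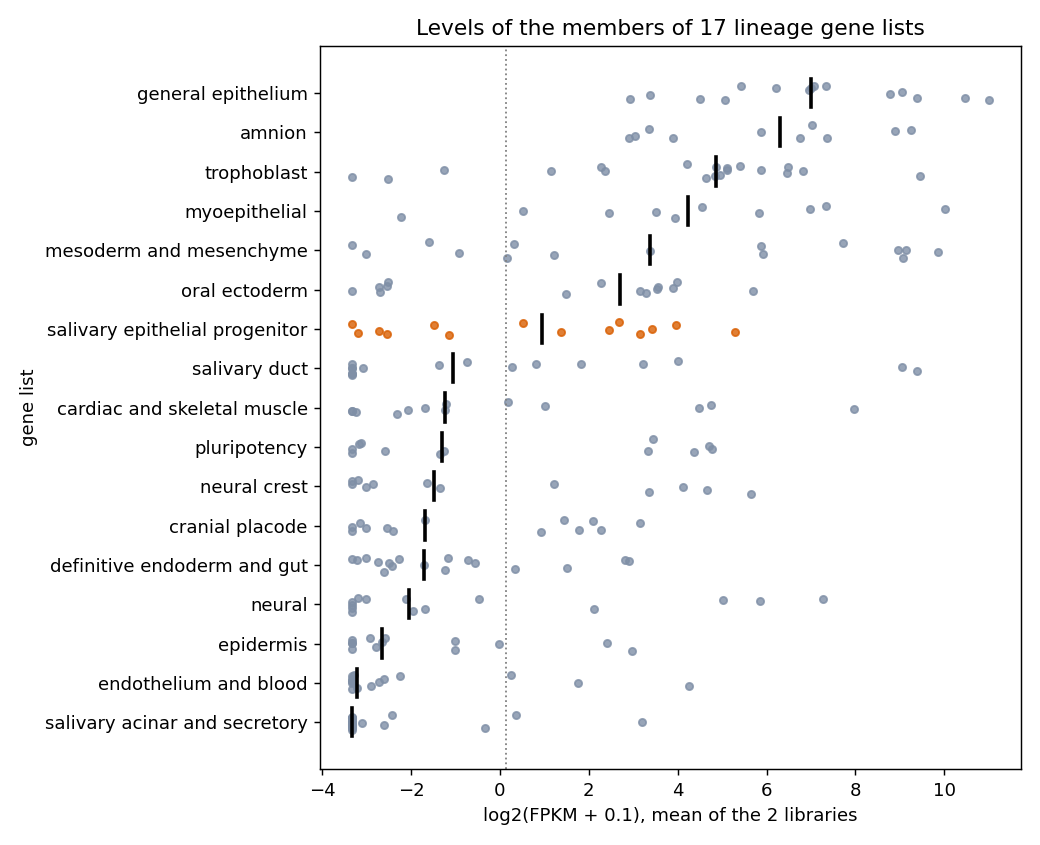
Each point is a gene of 1 of 17 lineage lists, on a log2(FPKM + 0.1) axis as the mean of the 2 libraries; bars are list medians, the dotted line is FPKM 1, and salivary progenitor genes are orange. The salivary progenitor median (0.94) lies below those of 6 of the 16 other lists, from oral ectoderm (2.71) to general epithelium (7.01).

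Set against the other lineage lists, the salivary progenitor list had the lower median for 6 of 16. The difference, salivary minus other on the log2 scale, was -6.06 ± 0.23 for general epithelium, -5.36 ± 0.29 for amnion, -3.94 ± 0.06 for trophoblast, -3.29 ± 0.30 for myoepithelium, -2.42 ± 0.23 for mesoderm and mesenchyme and -1.76 ± 0.15 for oral ectoderm. These 6 differences each exceeded their SD over the 2 libraries. Without genes on more than 1 lineage list, among them 7 of the 14 salivary genes, all 6 were smaller, among them -2.19 for trophoblast, -0.68 for mesoderm and mesenchyme and -0.61 for oral ectoderm, and with means in place of medians the oral ectoderm difference was -0.62. Levels of different genes share no biological scale, and 2 libraries allow no sign-flip p below 0.5, so no test was made.

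Trophoblast genes were detected for 16 of 19 members and amnion genes for 10 of 10. CGA, the alpha chain of chorionic gonadotropin (ENSG00000135346, chromosome 6, 87085498 to 87095406), reached 704 ± 127 FPKM, HAND1 89.97 ± 11, GATA3 59 ± 14 and CYP19A1 (aromatase) 29.3 ± 4.50. The beta chain genes CGB8 (118 ± 49.2) and CGB5 (92.5 ± 39.9) have near-identical copies and are uncertain individually. ELF5 was at 0.349 and 0.290. Of the amnion list, GABRP stood at 610 ± 19.7, IGFBP3 at 473 ± 11.1, BAMBI at 165 ± 1.78 and VTCN1 at 129 ± 2.03. Medians were 4.87 ± 0.23 and 6.31 ± 0.00, both at percentile 100 after rounding, and 3 of the 10 amnion genes also stand on another lineage list.

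Mesenchymal genes were detected for 10 of 15 members, led by COL3A1 (937 ± 168 FPKM), COL1A2 (575 ± 167), VIM (537 ± 16.9) and COL1A1 (495 ± 5.92), while PRRX1 (0.235 and 0.227) and TBXT (0.0379 and 0.0110) were low. Their median lay at percentile 98.1, and at 90.7 against genes with mean FPKM of at least 0.1. Of the muscle list, 4 of 13 members were detected, with the cardiac actin gene ACTC1 at 250 ± 1.69, MYL7 at 26.9 ± 2.53 and TNNT2 at 22.2 ± 0.362, and MYOD1 and MYOG at 0. Endothelial and blood genes were detected for 3 of 15 (CDH5 19.4 ± 4.36, KDR 3.29 ± 0.523, TEK 1.08 ± 0.00222) and endoderm genes for 4 of 17 (GATA6 7.42 ± 1.23, AFP 6.94 ± 0.151, APOA1 2.75 ± 0.260, CDX2 1.17 ± 0.0846). The 3 medians lay at percentiles 12.5, 0.030 and 4.56, or 0.160, 0 and 0 against that background. The endothelial percentile was 0.170 without replicate 1 and 0.130 without replicate 2.

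Neural genes were detected for 4 of 14 members, TUBB3 at 155 ± 17.9 FPKM, NES at 57.7 ± 4.53, STMN2 at 32.5 ± 1.64 and MAP2 at 4.24 ± 0.728, with PAX6 (0.265 and 0.165) low and SOX1 at 0. Neural crest genes were detected for 5 of 12, led by SNAI2 (50.3 ± 7.26), ETS1 (25.3 ± 1.33), ERBB3 (17.5 ± 2.41) and TFAP2B (10.3 ± 2.04), with PAX3 and PAX7 at 0. Placode genes were detected for 6 of 13, among them EYA2 (4.16 ± 0.0256) and FOXI3 (3.35 ± 0.0349), with CRYAA and NEUROG1 at 0. Their medians lay at percentiles 3.15, 8.74 and 7.40. Without replicate 1 they were 1.29, 5.27 and 4.46, and without replicate 2 that of the neural list was 4.89. Against genes with mean FPKM of at least 0.1 they were 0, 0.030 and 0. Of the pluripotency list, 5 of 12 members were detected: ZFP42 (27.5 ± 3.32), L1TD1 (26 ± 3.51), LIN28A (20.7 ± 1.00), DPPA4 (10.7 ± 0.746) and DNMT3B (9.94 ± 0.0219). POU5F1 was at 0.191 and 0.429, SOX2 at 0.449 and 0.214 and NANOG at 0 and 0.0231, and the median lay at percentile 10.9, or 0.060 against that background.

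Genes that respond to BMP, retinoic acid and WNT signalling, on which the factors given act, were then examined, with those of FGF signalling, for which no factor is listed. BMP4 was given until day 10 and retinoic acid for 2 days from day 10, before the harvest at day 16. BMP response genes were detected for 14 of 15 members, led by ID1 (166 ± 5.92 FPKM), BAMBI, ID3 (89.4 ± 15.6) and MSX2 (82 ± 18.6). Of these 15 genes, 3 also stand on a lineage list, among them BAMBI on the amnion list, so the list is no separate readout of the added BMP4. Retinoic acid genes were detected for 13 of 15, led by the retinoic acid carrier CRABP2 (188 ± 15.1), TGM2 (149 ± 0.0761), STRA6 (33.4 ± 5.56) and MEIS2 (23.9 ± 1.88), with the retinoic acid hydroxylase CYP26A1 at 9.94 and 5.26. WNT response genes were detected for 13 of 17, led by TNFRSF19 (52 ± 6.82) and CCND1 (50.4 ± 4.68), with AXIN2 at 13.5 ± 0.903, LEF1 at 7.99 ± 1.47 and SP5 at 0.0294 and 0.0263. FGF response genes were detected for 12 of 13, led by PHLDA1 (28 ± 2.27) and FOSL1 (20.2 ± 3.77). The 4 medians lay at percentiles 99.98, 97.8, 78.4 and 88. The retinoic acid list moved to 89.7, the WNT list to 39.7 and the FGF list to 63.7 against genes with mean FPKM of at least 0.1.

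Gland branching genes were detected for 13 of 23 members. The receptors ERBB2 (35.7 ± 4.83 FPKM), EGFR (27 ± 4.10) and FGFR1 (14.2 ± 0.865) stood beside FGFR2, while FGF10 (0 and 0.0186), FGF7 (0.314 and 0.114) and EDAR (0.124 and 0.118) were low. Basement membrane and integrin genes were detected for 17 of 18, with ITGB1 at 456 ± 17, COL4A2 at 296 ± 11.2 and COL4A1 at 261 ± 7.80 after FN1. Medians lay at percentiles 54.6 and 100, the former at 8.34 against genes with mean FPKM of at least 0.1 and 34.5 against annotated genes.

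HOX genes, which record position along the body axis, had mean FPKM of at least 1 for 13 of 39 members. HOXB2 was highest at 24.2 ± 1.18 FPKM, with HOXB3 at 11.7 ± 3.58 and HOXA3 at 6.63 ± 1.89. Among the others were HOXB6 (2.91 ± 0.611), HOXB4 (2.51 ± 0.299), HOXC8 (1.86 ± 0.819) and HOXC6 (1.07 ± 0.0750). They were 3 HOXA, 7 HOXB, 3 HOXC and 0 of 9 HOXD genes. Among paralogues 9 to 13, 0 of 16 members were detected, HOXC13 being highest at 0.758 and 0.575. Percentiles of the anterior, middle and posterior lists were 40.7, 38.3 and 0.070, the first 2 at 6.26 and 6.19 against genes with mean FPKM of at least 0.1 and the last at 0.220 with either library left out. Several neighbouring HOXB and HOXC genes overlap in the annotation.

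Developmental factors picked by symbol family included HAND1, GATA3, MSX2 and the ID genes above, with TBX3 at 50.2 ± 5.20 FPKM, KLF6 at 49.8 ± 0.911, PBX2 at 46.7 ± 2.53 and SOX4 at 37.2 ± 2.53. Proliferation genes were detected for 17 of 17 members (PCNA 59.7 ± 7.88, TYMS 41.8 ± 4.77, CCNB1 29.8 ± 6.71, UBE2C 26.2 ± 0.285). p53 targets were detected for 12 of 12, led by CDKN1A (185 ± 19.8) and GDF15 (68 ± 24.9), and stress genes for 15 of 15, led by HSPB1 (353 ± 83.2) and IER3 (74.7 ± 13). Glycolysis and hypoxia genes were detected for 12 of 14, led by ENO1 (453 ± 51.7) and ALDOA (307 ± 0.0936), with CA9 at 0. These 4 medians lay at percentiles 99.9, 99.99, 100 and 99.7. Of the control lists, housekeeping genes were detected for 16 of 16, mitochondrially encoded genes for 13 of 13, replication-dependent histones for 4 of 9 and genes of unrelated tissues for 2 of 25 (MBP 9.33 ± 0.727 and POMC 2.82 ± 0.107), at percentiles 100, 100, 11.4 and 0. The histone percentile was 20.3 without replicate 2 and 0.080 against genes with mean FPKM of at least 0.1. In total 14 of 34 lists lay at or above the 95th percentile, 5 of them lineage lists, where random lists give 1.7. Those random lists drew on all 22811 features, 3178 of them at 0 in both libraries. Lists of broadly transcribed genes, such as housekeeping genes, were likely to exceed them, so the count says little about these cells in particular.

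The last question was how closely the 2 libraries matched. Mitochondrially encoded genes were lower in library 2 for 12 of 13 members, by 1.58-fold at the median (MT-CO1 8831 and 5586 FPKM), and took 12.1% and 7.78% of all FPKM. Ribosomal protein genes were higher in library 2 for 66 of 77, by 1.33-fold at the median, and took 7.57% and 9.80%. Trophoblast genes were higher in library 2 for 0 of 16 members, with a median log2 difference, library 2 minus 1, of -0.35 (CGA 794 and 614). Of these 16, 8 were listed as having near-identical copies, without a comparison of sequences. These 8 had a median difference of -0.61, and the others were not summarised alone. Anterior HOX genes had -0.58 (HOXB3 14.3 and 9.21), or -0.25 with no filter on low values and -0.43 after rescaling to equal sums. Gland branching genes had -0.28, neural crest genes -0.28 and stress genes -0.18, and p53 targets had 0.24 (BAX 44.1 and 70.6).

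Of 30 lists compared, 7 lay outside the central 95% of random lists matched on level, where lists of unrelated genes give 1.5. Each random list drew its genes independently. Lists whose members vary together, such as the mitochondrial genes, fall outside more easily, so 1.5 is not the count to be awaited for these lists. The percentiles were 0 for mitochondrial genes, 0 for trophoblast, 0.030 for anterior HOX, 0.220 for branching, 1.05 for stress, 1.62 for neural crest and 99.6 for p53 targets. ERBB3 stands on both the branching and the neural crest list and is the middle member of each, so their medians are the same value and these 2 calls are not independent. The salivary progenitor list was inside at 6.70 (-0.19, higher in library 2 for 0 of 8 members) but outside with no filter on low values, at 1.20 (-0.26). Amnion genes were inside at 62.7. These compare 2 libraries, with no replicate on either side.

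**Figure D2:**
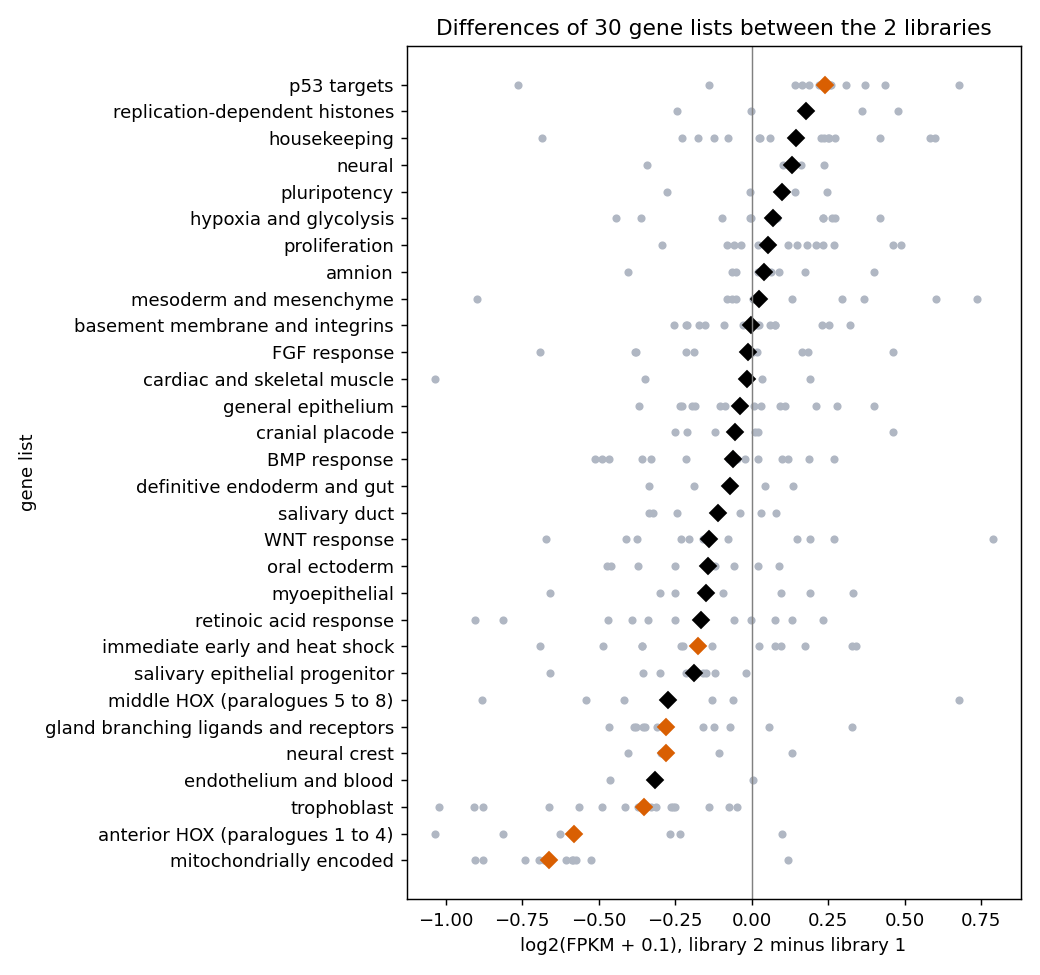
Grey points are list members with mean FPKM of at least 1, diamonds are list medians, on a log2 axis of library 2 minus library 1. The 7 orange diamonds lie outside the central 95% of matched random lists, from mitochondrial genes (-0.66) to p53 targets (0.24).

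Across 12647 genes with mean FPKM of at least 1, Pearson's r of log2(FPKM + 0.1) was 0.978 and Spearman's rho 0.983, with an SD of the log2 difference of 0.38; these are across genes, which are not independent replicates. More than 2-fold apart were 185 genes, 105 higher and 80 lower in library 2. The most extreme were mainly read-through models and models overlapping other genes: INO80B-WBP1 (5.97 and 0 FPKM), AL162417.1 (4.76 and 0), AL355312.5 (3.44 and 0) and BIVM-ERCC5 (3.13 and 0) in the lower direction. In the higher direction stood RPL36A-HNRNPH2 (0 and 24.7), an unnamed feature, AC023055.1 (0.0618 and 5.11) and AC131160.1 (0 and 2.53). Of the 145 annotated genes among the 185, 77 (53.1%) overlapped an exon of another gene, against 31.3% of all annotated genes compared. The count was 81 with a pseudocount of 1 (55 higher and 26 lower), 54 with mean FPKM of at least 5 (42 higher and 12 lower), 667 with both libraries rescaled to equal sums (329 higher and 338 lower) and 2008 with no filter (997 higher and 1011 lower), so the balance of directions depended on the setting.

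**Figure D3:**
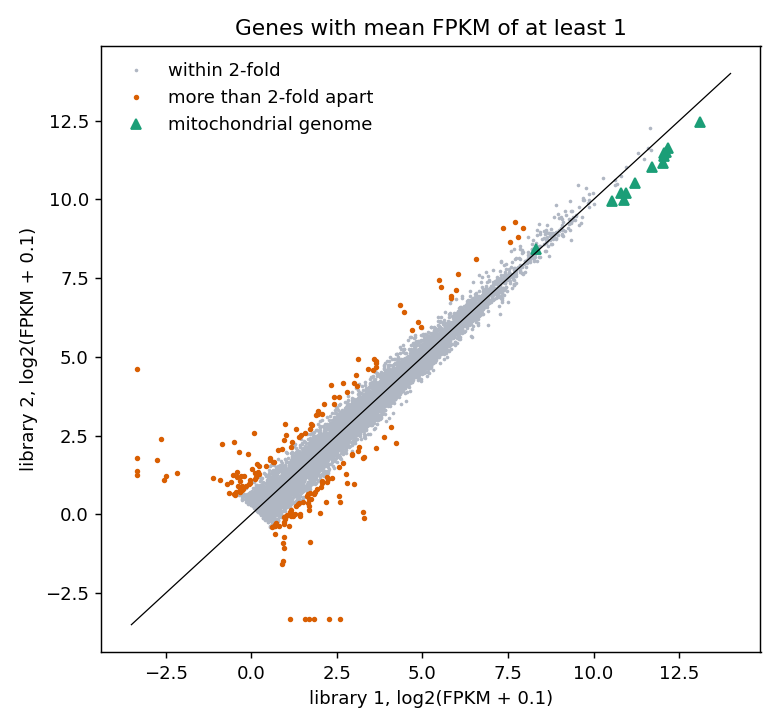
Each point is a gene with mean FPKM of at least 1, by its log2(FPKM + 0.1) in library 1 (horizontal) and library 2 (vertical); the line marks equal values. Orange points are the genes more than 2-fold apart, and 12 of 13 mitochondrial genes (green triangles) lie below the line.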

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

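The annotated-genes setting was chosen after seeing the data. Genes detected ranged from 8461 (FPKM of at least 5) to 16130 (at least 0.1), with 12582 to 12715 when either library was left out and 11725 for annotated genes. Pearson's r was 0.971 with a pseudocount of 0.01, 0.984 with 1 and 0.972 with no filter, outside the bootstrap interval over genes of 0.975 to 0.980. Genes more than 2-fold apart numbered 185, against 209 with a pseudocount of 0.01, 182 after centring, 81 with a pseudocount of 1, 54 with mean FPKM of at least 5, 667 after rescaling and 2008 with no filter. More were higher than lower in library 2, except after rescaling (329 higher and 338 lower) and with no filter (997 higher and 1011 lower). A higher pseudocount shrinks differences of low genes by construction, and the rescaled and unfiltered settings let in genes of lower FPKM. The number of lists at or above the 95th percentile was 14 in each setting except a background of genes with mean FPKM of at least 0.1, where 12 of the 14 were kept and mesenchyme and retinoic acid lists were lost. Single list percentiles moved by 10 or more, or across the 95th, in 18 of 238 cases, mostly with that background. The same 6 lineage lists stood above the salivary progenitor list in each setting, including without either library, with no sign change among the 16 differences, but their sizes moved by more than the SD in 57 of 64 cases, not counting those without a library, which cannot exceed it. Among the smallest were 0.39 for both duct and pluripotency with means, -0.61 for oral ectoderm and -0.68 for mesoderm without shared genes. The 7 lists apart between libraries were kept in each setting, where 7 to 10 were called, with anterior HOX at -0.25 with no filter against -0.58. The lists added were salivary progenitor, middle HOX and histones with no filter, and retinoic acid with a pseudocount of 1. Mitochondrial and ribosomal protein genes kept their directions after centring (medians -0.64 and 0.43) and rescaling (-0.65 and 0.42). No paired analysis was possible because there is 1 group. Depth, an estimate here, limits statements on genes near 0.0896 and 0.0802 FPKM.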

Other observations

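The gene groups of this paragraph were chosen after list values had been seen. Genes linked to epithelial-mesenchymal transition were detected for 10 of 12 members, with MMP2 at 413 ± 8.18 FPKM, TGFBI at 127 ± 5.48, TNC at 88.9 ± 0.619 and CDH2 at 35.6 ± 0.651 beside the E-cadherin gene CDH1 at 124 ± 13.8. Of the transcription factors on that list, SNAI2 stood at 50.3 ± 7.26 and ZEB2 at 5.85 ± 0.798. The others were low, with TWIST1 at 2.24 ± 0.152, SNAI1 at 1.28 ± 0.445, ZEB1 at 1.21 ± 0.227 and TWIST2 at 0 in both libraries. Tight and gap junction genes were detected for 10 of 12 (F11R 56.7 ± 8.89, TJP1 44 ± 5.99). Imprinted growth genes were detected for 12 of 14, with MEST at 186 ± 12.4, PEG10 at 84.5 ± 13.2 and CDKN1C at 64 ± 3.75. Steroid synthesis genes were detected for 8 of 10, with CYP11A1 at 31.7 ± 8.80 but STAR at 0.0756 and 0.125 and CYP17A1 at 0.0320 and 0.0455. Retroviral envelope genes were detected for 6 of 6 (ERVW-1 25.3 ± 8.11, ERVV-1 10.8 ± 2.97), and class I antigen presentation genes for 9 of 13, with HLA-C at 163 ± 18.1 and HLA-G at 0.392 and 0.20. These medians lay at percentiles 100, 97.9, 100, 99.4, 85.7 and 93.1.

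Of the patterns in these libraries 3 were weighed. The tests of near-identical copies, of residual stem cells and of mitochondrial fragments were chosen only after the result was seen. The controls that the design names were not analysed here, so the tests of biological explanations given below rest on these libraries alone. None of these tests compared the libraries with other cells or tissues.

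The first pattern is the abundance of amnion and trophoblast genes. Reads shared between near-identical gene copies are argued against for the amnion genes, none of which was listed with such a copy. Of these, 10 of 10 were detected, with a median at percentile 100. For the trophoblast genes the test does not decide, because it pooled both lists. The 19 members without such a copy, 18 of them detected, had a median at percentile 100 of random lists. The amnion genes among them were already known to be high, and the trophoblast genes were not tested alone. HAND1 (89.97 FPKM), GATA3 (59) and CYP19A1 (29.3), trophoblast genes not listed with such a copy, were nevertheless abundant. Shared reads are argued against for these genes, though not for the list as a whole. ELF5 was the only member of the 19 that was not detected. Cells of the placental syncytium may be a source, but the test written for it does not decide: 16 of 30 separate syncytial transcripts were detected, which meets the bound set beforehand, at least 15, yet 87.8% of random lists of annotated genes meet it too, a comparison added after the count was seen. Its most abundant members were TFPI2 (64.6 ± 2.04 FPKM), CAPN6 (63.9 ± 3.70) and SDC1 (57.4 ± 6.16), while 0 of 10 PSG genes were detected (at most 0.317) and the 4 placental lactogen and growth hormone genes stayed at or below 0.161. A quantifier can leave out copies of such families. It did not do so for all genes with copies here, since CGB8 and CGB5 stood at 118 and 92.5. Whether it did so for the PSG and lactogen genes is not known. Whether these transcripts came from separate placental or amniotic cells or from the same cells as the epithelial genes cannot be told apart, since bulk libraries were measured.

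The second pattern is that 5 of 12 pluripotency genes were detected. Residual pluripotent stem cells stay open as a source. The 7 other members had a median of 0 FPKM in library 1 and 0.0231 in library 2, at most 0.00108 of that of LIN28A, DPPA4, ZFP42, DNMT3B and L1TD1, but these sets were parted by their observed levels, so the ratio was bound to be low and decides nothing. POU5F1, SOX2 and NANOG, which stem cells transcribe, reached at most 0.449 FPKM in either library, and no stem cell library was analysed here to give the level that such cells would need. Expression of the 5 genes in the differentiated cells themselves stays open too and was not tested.

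The third pattern is the higher level of ribosomal protein genes in library 2. Fewer mitochondrial fragments raising all nuclear genes are argued against. The mitochondrial share of all FPKM fell only from 12.1% to 7.78%, too little to raise other genes by 1.33-fold. The median of other nuclear genes differed by -0.0191 (log2), but the shares already settle this by arithmetic, so that median is no separate test. Better recovery of short transcripts is too small: 1074 other genes under 700 nt exceeded 5351 genes over 2000 nt by 0.0670 at the median, beyond all of the random sets drawn but under the bound of 0.1. Ribosomal protein genes exceeded the 20 nearest other genes in length and level by 0.32 (quartiles 0.17 and 0.66, with 66 of 77 higher). The difference thus remained after matching on length and level. It is made of the same values as the pattern, so it is no separate support for a higher level of these transcripts as such. Single ribosomal protein genes had been seen among the largest differences when that test was written, the genes matched lay 0.18 lower in level at the median, and 1 library on each side leaves library preparation open.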
